A study of Mus musculus with 12 samples.

How the data were processed

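Total RNA from sorted colon epithelial cells of a mouse colon cancer model was hybridised to Affymetrix Mouse Gene ST 2.0 arrays, per the labels. The deposited values are log2 expression per transcript cluster, made by the authors with RMA in the oligo package, per the submitters' processing notes; the versions and options are not given in the sources used here. RMA in its usual form corrects the background, sets the arrays to a common distribution of probe signals and summarises the probes of a cluster. A change shared by most genes would therefore be removed, and differences of dim genes are compressed. Values of 12 arrays were used as deposited, and no column was left unmapped (0 columns). The groups were read from the sample titles: 6 samples of tumor epithelium and 6 of mucosa epithelium. The number of arrays limits the precision; scanner intensities and their background were not analysed here.

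Of 41345 transcript clusters, 23521 had 1 gene symbol in the platform annotation, 1820 had several and 16004 had none here. Only clusters with 1 symbol were named. Entrez identifiers of 23328 of them were found in the RefSeq gene table of assembly GRCm38.p6, all with the same symbol. The cluster with the highest mean over the 12 arrays stood for each of 22180 genes (1082 genes had more than 1 cluster). For Axin2, Lgr5, Cyp2c55 and Muc2, the named genes with a second cluster, the clusters had differences of the same sign. Coordinates are not given, since no genome build was stated.

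Differences between tumor and mucosa epithelium were tested gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 12 samples, with no block and no filter on dim genes. The p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. SE is limma's moderated standard error. The labels tie no replicate number to an animal, so the fit with that number as a block was an alternative. A set of 20 program lists and 10 lists of cell type markers, 437 memberships of which 408 were measured, was tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 30 lists. An estimated correlation, fry and an exact permutation of the list means were alternatives. Fry tests whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes. Some genes stand on several lists. Lists that share cells or genes are not independent of each other.

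The named genes follow a rule. They are Msh2 and Tgfbr2, and the 8 highest and 8 lowest log2 differences among genes past the threshold whose groups do not overlap, leaving out predicted genes and clones (1 called gene). From the lists come 2 members of each program list and 1 of each cell type list, those past the threshold by size or else those with the smallest p. The groups, the test, the lists, this rule and the first set of alternatives were set before the data were examined. Other members and genes named in the text, the pancreatic, islet and sex-linked lists and the gene families were chosen after their values were seen.

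The first set of alternatives held quantile normalization, centring of each array on its median, leaving out the 30% of genes with the lowest mean, the mean over a gene's clusters, each cluster on its own, eBayes with trend and robust options, and array weights. It also held the replicate number as a fixed or random block, a test against a 1.5-fold change, a minimum log2 difference of 1, a threshold of 0.01, the other list tests, and leaving out each sample in turn. Chosen after seeing the data were covariates for the pancreatic enzyme mean, the array spread, the macrophage marker mean and sex. So were leaving out the 5 libraries with pancreatic enzyme RNA, a block without both number 6 samples, the permutation of list means, and lists without Ly6g or Tff2.

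The gene test was checked on simulated values for 22180 genes in 6 against 6 samples of tumor and mucosa epithelium with 200 changed genes. It recovered 67% of those changed by a log2 of 1 and 96% of those changed by a log2 of 2, with 11 unchanged genes among 174 calls. Genes were drawn independently here too, without the variation that genes of real arrays share, so these shares need not hold for the real data. Each of the 4 list tests called the 3 shifted lists and none (0) of the 27 others in simulated data whose genes were independent, unlike those of real samples.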

Results

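The series compared epithelial cells sorted from colon tumors with epithelial cells sorted from tumor-free colon mucosa. Both came from a mouse model of colon cancer in which Msh2, a mismatch repair gene, and Tgfbr2, a TGF-beta receptor gene, were inactivated in the intestinal epithelium. Each group held 6 samples, 12 arrays in all, and each array gave a log2 expression value for 41345 transcript clusters. Of these, 23521 carried a single gene symbol and gave 22180 genes. The labels describe the mucosa as matched to the tumors but do not state that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be in part technical. The 6 arrays per group limit the precision, and the median standard error of a log2 difference was 0.18 over all genes. Array medians lay between 3.42 and 3.75 and the spread of values within an array (SD) between 1.73 and 1.97, and no pair of arrays held identical values.

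Both groups carry the same genotype, and the array's probes can lie outside the deleted part of a gene, so the level of a targeted gene does not check the labels here. Tgfbr2 stood at 5.19 ± 0.44 (SD, n = 6) in tumor epithelium and 4.72 ± 0.36 in mucosa epithelium, a log2 difference of 0.47 (SE 0.22, limma adjusted p = 0.551). Msh2 was not analysed here, because no transcript cluster names it alone.

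The comparison asks which genes differ between tumor epithelium and the tumor-free epithelium of the same model. In tumor epithelium 8 genes rose, among them Msln, which encodes the cell-surface glycoprotein mesothelin, Clu, which encodes the secreted chaperone clusterin, and Aldh1a3, an enzyme that makes retinoic acid. Clu rose from 5.65 ± 0.88 to 8.92 ± 0.77 (SD, n = 6), a log2 difference of 3.28 (SE 0.43) or 9.68-fold. The 31 genes that fell include the aldehyde dehydrogenase genes Aldh1a1 and Aldh1b1, the tight junction gene Cldn15, the mucin gene Muc2 and the proglucagon gene Gcg. Hsd3b3, a hydroxysteroid dehydrogenase gene, fell by 3.10 (SE 0.31), and Dpep1, a membrane dipeptidase gene, fell by 3.01 (SE 0.35).

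The other genes that rose were Khdc1a by 4.24 (SE 0.64), Msln by 3.45 (SE 0.55), and Aldh1a3 by 3.24 (SE 0.44). S100a14 of the S100 calcium-binding family rose by 1.97 (SE 0.30), the basement membrane laminin gene Lama3 by 1.82 (SE 0.31), the caveolar coat gene Cavin3 by 1.79 (SE 0.31) and Syt8 of the synaptotagmin family by 1.58 (SE 0.25). Of the genes that fell, the cytochrome P450 gene Cyp2c65 fell by 3.31 (SE 0.45), Vsig2 fell by 2.78 (SE 0.33), and Apol10a fell by 2.54 (SE 0.38). The sulfotransferase gene Sult1a1 fell by 2.46 (SE 0.35), the retinaldehyde dehydrogenase gene Aldh1a1 fell by 2.20 (SE 0.37) and the tight junction gene Cldn15 fell by 2.19 (SE 0.24). The adjusted p-values of these 16 genes ran from 0.00386 (Hsd3b3) to 0.0427 (Cavin3). Further genes that fell, with their log2 differences, include Aldh1b1 (−2.07), Mettl7b (−2.07), the pyruvate dehydrogenase kinase gene Pdk4 (−1.99) and Irf8 (−1.82). The potassium channel subunit gene Kcne3 (−1.57), the inflammasome receptor gene Nlrp6 (−1.58), the peptidase gene Dpp4 (−1.38) and the retinol saturase gene Retsat (−1.23) fell as well. Khdc1a, Cyp2c65, Hsd3b3 and Apol10a belong to families of near-identical copies, so their signal cannot be assigned to 1 copy with certainty.

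The 39 genes passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment over all 22180 genes, and 2031 genes had an unadjusted p under 0.05, 644 higher and 1387 lower in tumor epithelium. In 38 of the 39 genes no tumor value overlapped a mucosa value. Over all genes, 195 showed no overlap, where chance gives 0.216% of genes, or 48.0. The count depended on single libraries: it was 13, 73, 10 and 9 without tumor 2, 3, 4 and 5, and 12, 7, 23, 19, 12 and 62 without mucosa 1, 2, 3, 4, 5 and 6. Aldh1b1, Cldn15, Clu, Dpep1, Gcg, Hsd3b3 and Vsig2, 7 genes, passed whichever library was left out. A fit with the replicate number as a block called 24 genes, 16 of them among the 39. With the 5 libraries that hold pancreatic enzyme RNA left out, 1 gene passed, and 1 other gene with the macrophage marker mean as a covariate; neither is among the 39. In both of these fits all 39 genes kept their direction and had an unadjusted p under 0.05. The 39 were picked from these same arrays, so this is no separate test of them. With the pancreatic enzyme mean as a covariate 8 of the 39 passed, all of them lower. With the spread of each array as a covariate 170 passed, of which 44.7% were lower, against 79.5% of the 39.

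**Figure D1:**
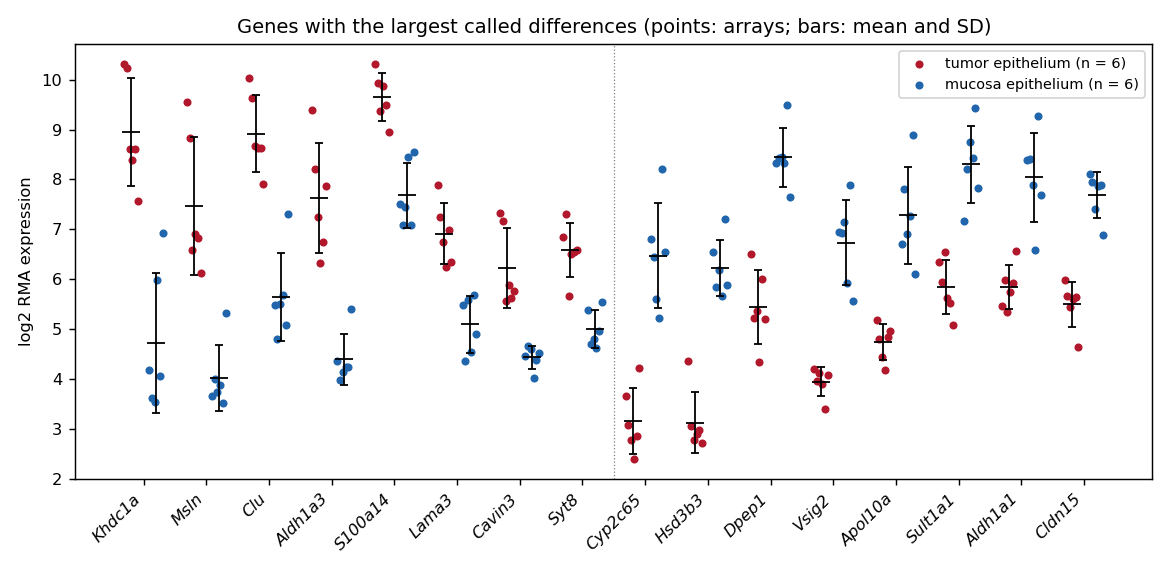
Log2 RMA expression (vertical axis) of the 8 genes with the highest and the 8 with the lowest log2 difference (horizontal axis). They were taken from called genes whose groups do not overlap, leaving out predicted genes and clones (1 called gene). Points are arrays, tumor epithelium in red and mucosa epithelium in blue (n = 6 each), and bars give the mean and SD. The lack of overlap in these 16 genes follows from that choice. Clu averages 8.92 in tumor and 5.65 in mucosa epithelium.

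Genes of the fetal and regenerative epithelium list, which are used by the fetal gut and by repairing epithelium, rose as a group in tumor epithelium. Their mean log2 difference was 1.07 over the 12 measured of 16 listed members, and 11 of the 12 were higher. Ly6a, Tacstd2, Spp1 and Areg of this list were not among the measured members. Msln and Clu rose over all genes, and 5 members rose adjusted over the list alone, which adds Anxa1 (1.32), Anxa3 (1.5) and the YAP target Ccn2 (1.54). The YAP targets Ccn1, the 1 lower member, and Ankrd1 stood at −0.66 (SE 0.34) and 0.27 without passing. Genes of the inflammatory epithelium list also rose as a group, by a mean of 0.64 over 20 members, 15 of them higher. None of its members passed over all genes and 5 rose adjusted over the list alone. These were the chemokine genes Cxcl2 (1.53) and Cxcl5 (1.14), the interleukin-1 genes Il1a (1.89) and Il1b (1.20) and the prostaglandin synthase gene Ptgs2 (1.19). The antimicrobial lectin genes Reg3g and Reg3b stood at −1.61 and −0.64 without passing. Genes of the enteroendocrine list, the hormone-producing cells of the gut, fell as a group by a mean of 0.67 (12 of 14 members lower). Gcg fell by 1.77 (SE 0.20, adjusted p = 0.00496), and 5 members fell adjusted over the list alone, with secretin (Sct, −1.56), the granins Chgb (−1.42) and Chga (−1.27) and the prohormone convertase Pcsk1 (−0.62) beside it.

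The gastric and metaplasia list rose by a mean of 0.34, with 14 of 16 members higher. No member passed over all genes and 1 rose adjusted over the list alone, Anxa1, an annexin gene that is not specific to stomach and is also on the fetal and regenerative list, as is Krt7 (0.39). The gastric mucin genes Muc5ac and Muc6 differed by 0.20 and 0.05 from mucosa levels of 3.19 and 3.12. These levels, and those of Gkn2, Gkn3, Anxa10, Cldn18, Pgc, Sox2 and Tff2, lay below the mean mucosa array median of 3.54. Differences of Gkn2, Gkn3, Anxa10, Cldn18, Pgc and Sox2 lay between −0.04 and 0.24, so their share in the count of higher members says little. Tff2, a trefoil factor gene of stomach and pancreas, differed by 1.69 (SE 0.68, adjusted p = 0.458). It reached 4.62 to 7.52 in the 5 libraries with pancreatic enzyme RNA against 2.55 to 4.34 in the other 7, values chosen for mention after they were seen. The 4 lists named so far, of 30 tested, held in camera both with its preset correlation of 0.01 and with an estimated correlation (adjusted p = 0.0449 for each). Without Tff2 the gastric and metaplasia genes had an adjusted p = 0.0523 with an estimated correlation. In an exact two-sided permutation test of the list means 6 lists passed: the fetal, enteroendocrine, gastric and mesenchymal transition lists (adjusted p = 0.0325 each), the macrophage list (adjusted p = 0.039) and the neutrophil list (adjusted p = 0.0433). The inflammatory list did not (adjusted p = 0.0649).

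Camera with the preset correlation called 18 of the 30 lists, 10 up and 8 down. It also called a median of 7 lists in random splits of the same 12 arrays. List tests with libraries left out or with a covariate used this preset correlation too. The 14 calls of the lists that follow do not hold with an estimated correlation. With the macrophage marker mean as a covariate 9 of the 18 calls remained. The gastric and metaplasia genes no longer passed (adjusted p = 0.152), at a mean of 0.37 against 0.34 without the covariate. Nor did the mesenchymal transition genes (mean 0.081, adjusted p = 0.913), DNA replication genes (−0.30, 0.0551), absorptive colonocyte genes (−0.095, 0.381), ribosome biogenesis genes (0.12, 0.567), neutrophil markers (0.31, 0.314), fibroblast markers (−0.19, 0.117) and B and plasma cell markers (−0.095, 0.359). Among the lists that still passed, the means were 0.35 for the inflammatory epithelium genes, −0.30 for the intestinal stem cell genes, −0.39 for the mitosis genes, −0.28 for the fatty acid oxidation genes and 0.41 for the TGF-beta pathway genes. The macrophage list itself cannot be tested in that fit.

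**Figure D2:**
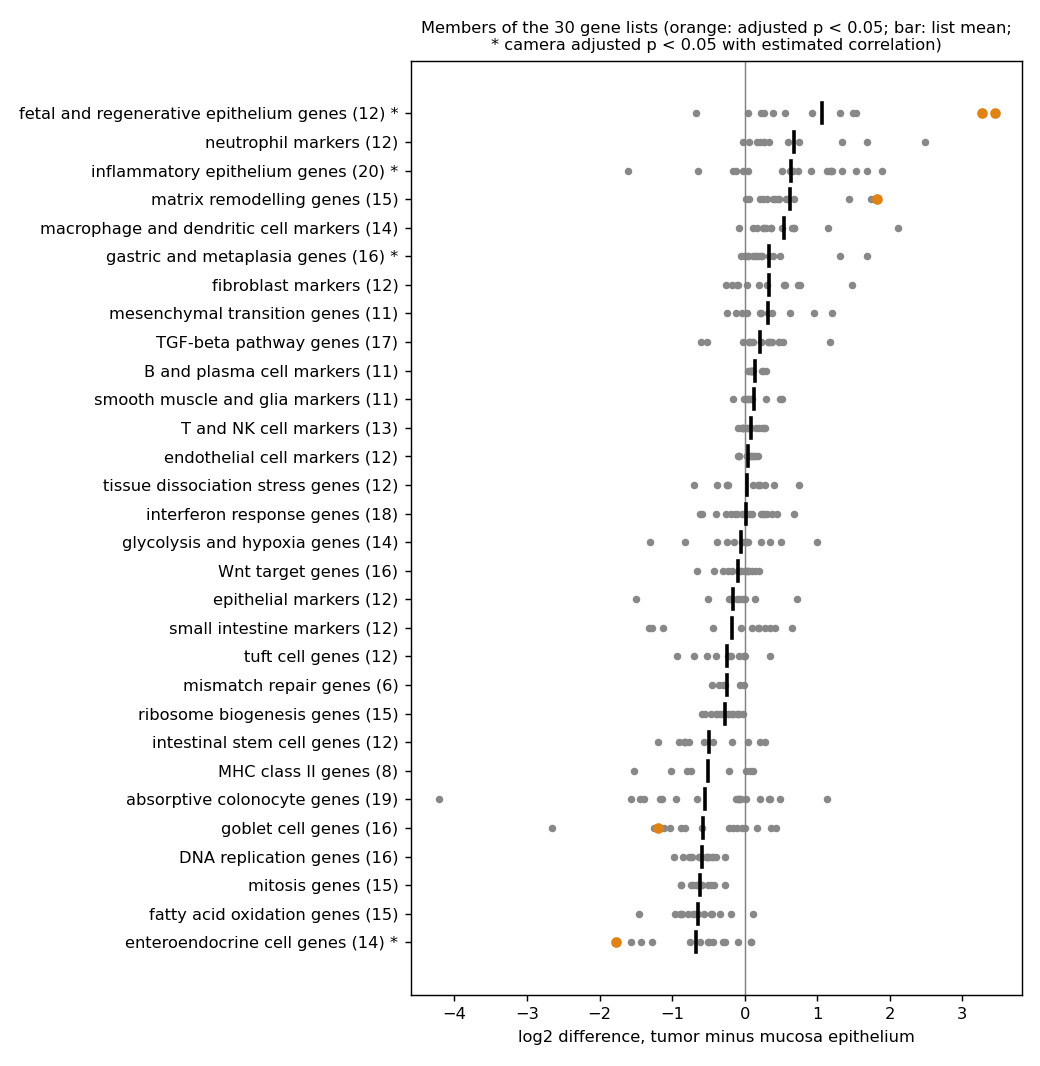
Log2 difference, tumor minus mucosa epithelium (horizontal axis), of every measured member (points) of the 30 gene lists (vertical axis, number of measured members in parentheses). Bars mark list means, orange points members with an adjusted p under 0.05 over all genes and stars the 4 lists that pass with an estimated correlation; list means run from −0.67 (enteroendocrine cell genes) to 1.07 (fetal and regenerative epithelium genes).

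Among the lists of differentiated and stem cells, the goblet cell genes fell by a mean of 0.57 with the preset correlation (12 of 16 lower; adjusted p = 0.108 with an estimated correlation). Muc2, the main secreted mucin of the colon, fell from 11.5 ± 0.33 to 10.4 ± 0.43 (SD, n = 6; log2 difference −1.20, SE 0.21, adjusted p = 0.0442). Adjusted over the list alone, 6 members fell, among them the resistin-like Retnlb (−2.65) and the goblet cell transcription factor gene Spdef (−1.03). The absorptive colonocyte genes fell by a mean of 0.55 (adjusted p = 0.410 with an estimated correlation), with a median of −0.09. None passed over all genes. Adjusted over the list alone 5 fell and 1 rose, Clca4a (1.13). Those that fell were the cytochrome P450 gene Cyp2c55 (−4.22, SE 0.80, adjusted p = 0.0602 over all genes), the guanylin gene Guca2a (−1.16, SE 0.22), Slc9a3, Mep1a and Car4. The list's call ended without tumor 4 (mean −0.49), tumor 6 (−0.42), mucosa 3 (−0.52), mucosa 5 (−0.49) or mucosa 6 (−0.55). Without the 5 libraries with pancreatic enzyme RNA the mean of the absorptive colonocyte genes was −0.94 (adjusted p = 0.000284). The intestinal stem cell genes fell by a mean of 0.50 (adjusted p = 0.124 with an estimated correlation), none over all genes and 3 adjusted over the list alone, Lgr5 (−0.76), Ascl2 (−0.56) and Smoc2 (−1.19). The 12 tuft cell genes did not pass (mean −0.24, adjusted p = 0.0954), with no member past the threshold over all genes or adjusted over the list alone. Sh2d6 stood at −0.93 (SE 0.49) and Rgs13 at −0.70 (SE 0.38). Without mucosa 5 the means of the tuft cell genes, Sh2d6 and Rgs13 differed by −0.069, −0.47 and −0.30, and the list passed without tumor 6 (−0.32), mucosa 2 (−0.29) or mucosa 6 (−0.30). The 16 Wnt target genes did not pass either (mean −0.09, adjusted p = 0.744), with none past the threshold over all genes or adjusted over the list alone. Axin2 stood at −0.30 (SE 0.18) and Apcdd1 at 0.20 (SE 0.13).

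All 15 mitosis genes and all 16 DNA replication genes had lower means in tumor epithelium, and both lists fell with the preset correlation (means −0.62 and −0.59; adjusted p = 0.410 and 0.348 with an estimated correlation). No member of either passed over all genes or adjusted over the list alone. Cdc20 stood at −0.88 (SE 0.31), Aurka at −0.72 (SE 0.31), Mcm3 at −0.97 (SE 0.38) and Pcna at −0.43 (SE 0.17). The mucosa libraries varied widely in the mitosis genes, with list means from 4.63 in mucosa 5 to 7.21 in mucosa 1. Without mucosa 1 the mean differences of the mitosis genes and DNA replication genes were −0.33 and −0.34, and both lists still passed. Without the 5 libraries with pancreatic enzyme RNA they were −0.35 (adjusted p = 0.0618) and −0.38 (adjusted p = 0.0147). The fatty acid oxidation genes fell by a mean of 0.65 (14 of 15 lower; adjusted p = 0.108 with an estimated correlation). None passed over all genes and 7 fell adjusted over the list alone, led by the mitochondrial thiolase gene Acaa2 (−1.45, SE 0.29) with Ehhadh at −0.88 (SE 0.22). The ribosome biogenesis genes fell by a mean of 0.27 (adjusted p = 0.580 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. Nolc1 stood at −0.55 (SE 0.33) and Utp20 at −0.38 (SE 0.25). The list's call ended without tumor 4 (mean −0.24), tumor 5 (−0.26), tumor 6 (−0.13), mucosa 1 (−0.089) or mucosa 2 (−0.21). The glycolysis and hypoxia genes did not pass (mean −0.05, adjusted p = 0.984) and had no member past the threshold over all genes or adjusted over the list alone. Their median (0.01) and camera's direction were up while the mean was below 0. Bnip3 stood at 1.0 (SE 0.37) and Adm at −1.31 (SE 0.58).

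The matrix remodelling genes rose by a mean of 0.63 with the preset correlation, all 15 members higher (adjusted p = 0.0995 with an estimated correlation). Lama3 rose over all genes and was also the 1 member past the threshold adjusted over the list alone. The mesenchymal transition genes rose by a mean of 0.33 (adjusted p = 0.0995 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. The matrix protein genes Fn1 and Sparc stood at 1.20 (SE 0.38) and 0.96 (SE 0.36). The TGF-beta pathway genes rose by a mean of 0.22 (14 of 17 higher; adjusted p = 0.214 with an estimated correlation). None passed over all genes and 1 rose adjusted over the list alone, the feedback inhibitor gene Pmepa1 (1.18, SE 0.24), with Skil at 0.48 (SE 0.21). The mean of the TGF-beta pathway genes was 0.14 without tumor 1, and 0.044 (adjusted p = 0.187) without the 5 libraries with pancreatic enzyme RNA. The interferon response genes (mean 0.03, adjusted p = 0.440), the MHC class II genes (mean −0.51, adjusted p = 0.0954) and the mismatch repair genes (mean −0.24, adjusted p = 0.0820) did not pass. None of their members passed over all genes or adjusted over the list alone. Their named members were Ifit1 at 0.68 (SE 0.30), Rsad2 at 0.38 (SE 0.20), H2-DMa at −0.80 (SE 0.37), H2-Aa at −1.01 (SE 0.53), Msh6 at −0.45 (SE 0.21) and Mlh3 at −0.29 (SE 0.21). With 1 library left out, the interferon response genes passed without tumor 3 (mean 0.16), the MHC class II genes without tumor 4 (−0.60), mucosa 1 (−0.70) or mucosa 3 (−0.65), and the mismatch repair genes without tumor 1 (−0.30) or mucosa 5 (−0.31). Without the 5 libraries with pancreatic enzyme RNA the mean of the interferon response genes was −0.66 (adjusted p = 0.000217) and Rsad2 stood at −0.18.

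Markers of other cell types were measured as well, since a sort can carry some of them over. The macrophage and dendritic cell markers rose by a mean of 0.54, from 4.06 ± 0.14 to 4.6 ± 0.40 (SD, n = 6; adjusted p = 0.108 with an estimated correlation). None passed over all genes and 3 rose adjusted over the list alone, C1qc (0.65), Mrc1 (0.68) and Lyz2 (2.11, SE 0.55). The fetal, inflammatory, matrix and mesenchymal lists were higher in the same group. Within the 6 tumor libraries the macrophage mean and the fetal list mean had Pearson's r = −0.609 (exact permutation p = 0.193) and Spearman's rho = −0.829 (exact permutation p = 0.0583), and r was 0.206 without the 2 libraries farthest from the median. Within the 6 mucosa libraries r was 0.898 (exact permutation p = 0.0139, adjusted over these 2 relations 0.0278) and rho 0.943 (exact permutation p = 0.0167), and r was 0.566 without the 2 farthest. The neutrophil markers rose by a mean of 0.68 (adjusted p = 0.0995 with an estimated correlation). None passed over all genes and 1 rose adjusted over the list alone, Ly6g (2.49, SE 0.46, adjusted p = 0.0549 over all genes), a member of a family of close copies. The neutrophil receptor genes Csf3r and Cxcr2 averaged 2.78 and 3.49 in tumor and 2.52 and 3.29 in mucosa epithelium and did not pass over all genes or adjusted over the list alone, although every tumor value of Csf3r was above every mucosa value. S100a8 (1.68) and S100a9 (1.35), which the inflammatory list shares, did not pass. The fibroblast markers rose by a mean of 0.33 (adjusted p = 0.410 with an estimated correlation; Col1a1 0.77, SE 0.29). The B and plasma cell markers rose by a mean of 0.14, from 3.30 in mucosa to 3.44 in tumor epithelium (adjusted p = 0.339 with an estimated correlation). These levels lie below the mean array medians of 3.54 and 3.59. Mzb1 stood at 0.29 (SE 0.17). Neither list had a member past the threshold over all genes or adjusted over the list alone. The fibroblast call ended without tumor 2 (0.26), tumor 4 (0.26), tumor 6 (0.24), mucosa 3 (0.25) or mucosa 6 (0.31), and the B and plasma cell call without tumor 4 (0.11), tumor 6 (0.081) or mucosa 5 (0.098).

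The T and NK cell markers (mean 0.09, adjusted p = 0.0954; Gzmb 0.19) and the endothelial cell markers (mean 0.05, adjusted p = 0.247; Cldn5 0.13) did not pass. Neither did the smooth muscle and glia markers (mean 0.13, adjusted p = 0.0954; Myh11 0.29) and the tissue dissociation stress genes (mean 0.03, adjusted p = 0.667; Fosb 0.75). None of the members of these 4 lists passed over all genes or adjusted over the list alone. Without mucosa 6 the T and NK cell markers (mean 0.14) and the smooth muscle and glia markers (0.18) passed. The epithelial markers stood at 9.37 ± 0.42 in tumor and 9.53 ± 0.23 in mucosa epithelium (SD, n = 6; adjusted p = 0.278). None of them passed over all genes and 1 fell adjusted over the list alone, the intestinal homeobox gene Cdx2 (−1.50, SE 0.39), while Epcam, the surface marker of epithelium, stood at −0.11 (SE 0.18). The small intestine markers did not pass (adjusted p = 0.998), with no member past the threshold over all genes or adjusted over the list alone. Their mean was −0.17 while the median (0.14) and camera's direction were up, and Slc5a1 stood at −1.13 (SE 0.36).

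RNA of 8 pancreatic digestive enzyme genes stood high in 5 of the 12 libraries. The genes were Cpa1, Cpb1, Ctrb1, Ctrl, Prss2, Pnliprp1, Cel and Cela3b, chosen after the values were seen. Their mean stood at 7.60 to 9.79 in tumor 1, tumor 2, tumor 4, tumor 5 and mucosa 1 and at 3.42 to 3.91 in the other 7 libraries. Of 6 further secretory genes of the pancreas, Reg1, Rnase1, Gp2 and Clps were higher in each of these 5 libraries than in any other, and Sycn and Cela1 were not. Sycn lay between 10.6 and 11.5 in the 5 and between 7.55 and 12.1 in the others, and Cela1 between 7.89 and 9.90 and between 4.67 and 8.49. Genes of pancreatic acinar transcription factors (Ptf1a, Rbpjl and Bhlha15), the islet hormone genes Ins2 and Iapp and the islet transcription factor gene Pdx1 lay between 2.25 and 4.61 in all 12 libraries. The enzyme RNA sits in 4 tumor libraries and 1 mucosa library, beside each list that is higher in tumor epithelium. Without these 5 libraries the mean of the fetal and regenerative epithelium genes differed by 0.68 and that of the inflammatory epithelium genes by 1.07, from 2 tumor and 5 mucosa libraries, and those of the gastric and metaplasia genes, matrix remodelling genes and neutrophil markers by 0.22, 0.37 and 1.27.

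**Figure D3:**
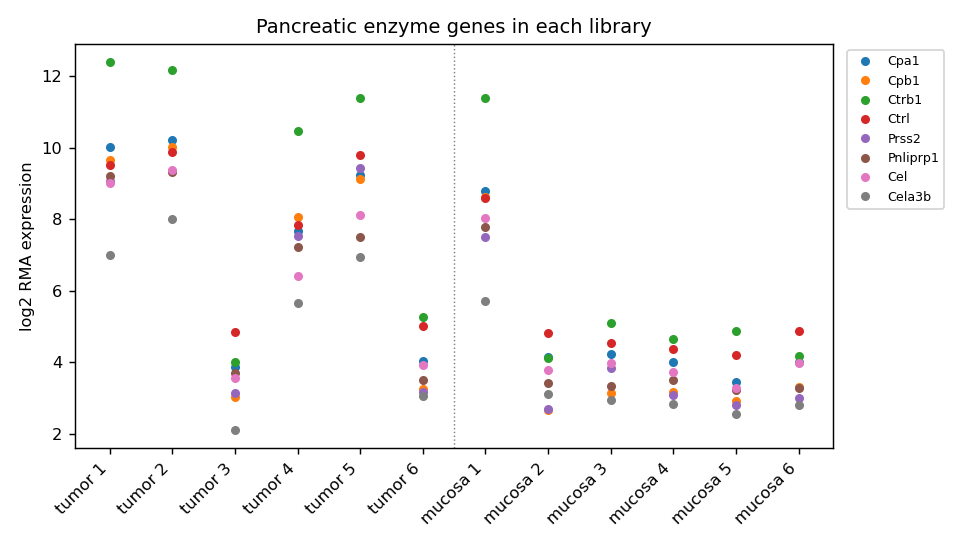
Log2 RMA expression (vertical axis) of 8 pancreatic enzyme genes in each of the 12 libraries (horizontal axis), with a point per gene. In tumor 1, 2, 4 and 5 and mucosa 1 the points lie between 5.65 and 12.4, and in the other 7 libraries between 2.13 and 5.26.

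The first principal component of the arrays held 39.2% of the variance and did not separate the groups (exact permutation p = 0.301, adjusted over 5 array measures 0.505). It tracked the spread of values within an array, with Pearson's r = −0.973 over 12 arrays (permutation p = 1e-05, the smallest that 100000 resamples can give) and Spearman's rho = −0.944 (permutation p = 3e-05). Pearson's r was −0.954 without the 2 arrays farthest from the median spread, −0.992 within the tumor and −0.948 within the mucosa arrays. The second component, with 14.3% of the variance, separated tumor from mucosa epithelium. Its exact two-sided permutation p was 0.00216, the smallest that 6 against 6 allows (adjusted 0.0108). The component is not set apart from pancreatic enzyme RNA. Tumor 1 and tumor 2, with the highest enzyme means, stood highest (47.8 and 32.7), and mucosa 1 was the highest mucosa array (−10.4). Tumor 3, without that RNA, was the lowest tumor array (−6.16), but tumor 6, also without it, stood above tumor 4 (15.8 against 10.5).

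**Figure D4:**
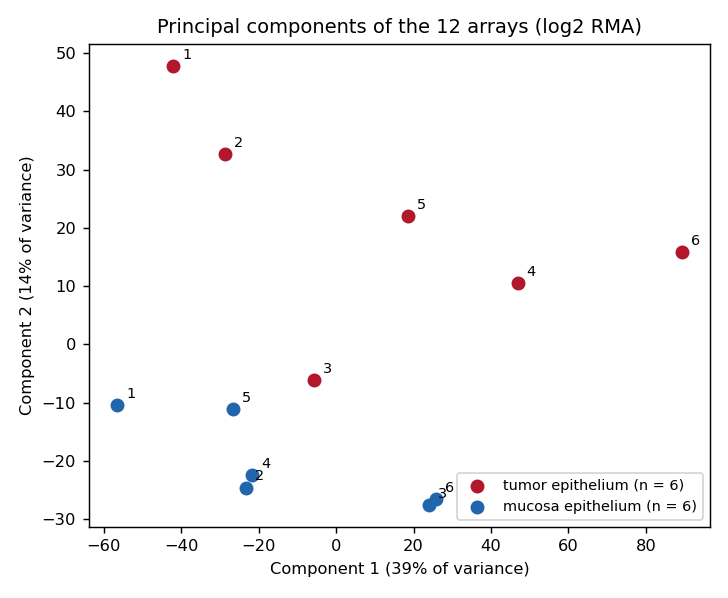
First (horizontal axis) and second (vertical axis) principal component of the 12 arrays from their log2 RMA values, tumor epithelium in red and mucosa epithelium in blue (n = 6 each), numbered by replicate. The 6 tumor arrays lie above the 6 mucosa arrays on the second component (14.3% of variance), while both groups spread along the first (39.2%).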

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

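The tests of pancreatic enzyme RNA, of the fetal and regenerative list and of sex-linked RNA in this part were chosen only after the result was seen.

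In 14 of 186 checks of a group of 6 samples, 1 sample lay apart from the other 5 by more than a gap rule at the 95% level allows, where chance gives about 1 in 20, or 9.3. Mucosa 6 lay apart, above the other mucosa samples, in 3 genes that rose in tumor epithelium. Msln stood at 5.33 against 3.53 to 4.0 in the other 5 and Clu at 7.32 against 4.81 to 5.68. Aldh1a3 stood at 5.40 against 3.98 to 4.36. Within the rule, mucosa 6 was also the highest mucosa sample for Khdc1a (6.93), S100a14 (8.55) and Syt8 (5.55), but not for Lama3 or Cavin3. It was the lowest for Dpep1 (7.65), Vsig2 (5.55), Apol10a (6.10) and Cldn15 (6.89), but not for Cyp2c65, Hsd3b3, Sult1a1 or Aldh1a1. Mucosa 5 held more tuft cell RNA than the other mucosa samples, with Sh2d6 at 8.15 against 4.87 to 6.05, Rgs13 at 5.39 against 2.83 to 3.23 and the tuft cell list mean at 4.79 against 3.63 to 3.88. Its TGF-beta pathway mean stood at 5.56 against 4.86 to 5.11. Mucosa 4 had the lowest Cyp2c55 (7.79 against 10.4 to 11.5) and the highest Cxcl2 (8.28 against 6.18 to 6.96), and mucosa 3 the lowest inflammatory list mean (4.63 against 5.29 to 5.64). Among the tumors, Hsd3b3 stood at 4.36 in tumor 1 against 2.71 to 3.06, Vsig2 at 3.40 in tumor 5 against 3.90 to 4.2, and Guca2a at 10.2 in tumor 3 against 11.1 to 11.5. In tumor 6 the small intestine marker mean stood at 5.33 against 4.24 to 4.51, and Lyz1, a lysozyme gene of Paneth cells with the near-identical copy Lyz2, at 9.63 against 4.35 to 6.09. Tumor 6 also had the lowest array weight of the 12 (0.366), the lowest mean correlation with the other arrays (0.887) and the value farthest from 0 on the first principal component, and without it 48 genes passed, 30 of them among the 39.

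The number of changed genes exceeds what the other splits drawn from the 12 samples gave. Of 100 splits drawn from 462, the real one included, 1 called as many genes, the real split itself. It called 39 and the highest of the others 4, so such a count was rare among the splits drawn. With 100 splits the smallest share is 1 in 100. The splits also treat the 12 samples as independent, which the labels do not state. For the lists with the preset correlation, 2 of the 100 splits called as many: the real split called 18 and the highest of the others also 18, with a median of 7. A count of lists of this size is rare by chance but calls of single lists are not, since members of a list vary together between samples. With an estimated correlation the real split called 4 lists and the highest of the others 1.

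RNA of pancreatic digestive enzymes stood out in tumor 1, 2, 4 and 5 and mucosa 1, and a program of every tumor is argued against, since 4 of the 6 tumor libraries and 1 mucosa library lay above the midpoint. Pancreatic tissue or its RNA, mixed in at different amounts, is a candidate source. The 8 genes were picked for this pattern, so they cannot test it. Of 6 further secretory genes 4 followed it (Reg1, Rnase1, Gp2 and Clps), and Sycn and Cela1 did not. Sycn and Cela1 stood at up to 12.1 and 8.49 in the libraries without enzyme RNA. Added RNA need not lift such genes above every other library, so Sycn and Cela1 cannot decide the source. Ctrb1 lay between 10.5 and 12.4 in the 5 libraries and between 4.01 and 5.26 in the others. The sort for epithelial cells would not remove pancreatic epithelium, and whether the RNA entered with the tissue or later, and whether some tumors make it themselves, stays open.

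The fetal and regenerative list was higher in tumor epithelium by a mean of 1.07 (SE 0.22). Pancreatic RNA and array spread were argued against as the whole cause. The difference stayed above 0 by over 2 SE without the 5 libraries with pancreatic enzyme RNA (0.68, SE 0.19). It also did so with the array spread as a covariate (1.23, SE 0.16). For pancreatic RNA the argument rests on 2 tumor against 5 mucosa libraries. Tumor 3 and tumor 6 had list means of 6.55 and 6.06, against 5.42 to 5.87 in these mucosa libraries. Tumor 6 had the lowest array weight of the 12 (0.366), so the argument is weak. Macrophages and dendritic cells stay open: the difference was 1.37 (SE 0.28) with their marker mean as a covariate, and with a slope per group it was 0.99 (SE 0.35) at the mean marker level of all libraries and 0.50 (SE 0.58) at that of the tumor libraries, 4.6, which is above every mucosa library's. Its members Clu and Msln no longer passed over all genes in the first of these fits, at 2.62 (SE 0.61) and 2.26 (SE 0.45, adjusted p = 0.748 each) against 3.28 (SE 0.43) and 3.45 (SE 0.55) in all 12 libraries, with fewer samples, and not with the macrophage covariate, at 3.54 (SE 0.60) and 3.99 (SE 0.77), where the SE grew. That tumor epithelium of this model turns on genes of fetal and repairing epithelium is a hypothesis these values may go with, found and tested on the same data; pancreatic RNA as part of the size, and a shift in the kinds of epithelial cell sorted, stay open.

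Of the 12 libraries 3 stood apart in sex-linked RNA: Xist, the RNA of the inactive X chromosome, stood at 3.94 in tumor 5, 4.73 in tumor 6 and 4.57 in mucosa 5, and at 8.66 to 10.6 in the others. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty stood at 5.04, 3.59 and 5.5 in these 3 and at 2.09 to 2.46 in the others. If replicate numbers marked the same animal, both samples of a number would agree; in 1 of the 6 numbers, number 6, they differed, which argues against it for that number, and it stays open for the other 5, since a share of 0.2 of the pairings of these would agree as well. If the tumors and mucosa came from the same 6 animals under other numbers, the groups would hold equally many samples with Y-linked RNA; they differed by 1 (2 tumors against 1 mucosa). A single mislabelled or mixed sample and mucosa from other animals stay open, and no biological explanation was tested.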

How the results depend on the processing

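The covariates, the left-out sets of libraries, the block without number 6 and the permutation of list means were chosen only after the results were seen. In all gene-level fits run, the 39 genes kept their direction, though they were picked from the same arrays. The count of changed genes was 74 with quantile normalization, 11 with arrays centred on their median, 59 without the dimmest genes and 112 with array weights. It was 4 in a test against a 1.5-fold change (Cldn15, Dpep1, Hsd3b3 and Vsig2), 6 at an adjusted p of 0.01 and 18 with each transcript cluster on its own, 5 of them without a symbol here. It ran from 7 (without mucosa 2) to 73 (without tumor 3) when 1 sample was left out. The added settings gave 8 with the pancreatic enzyme mean as a covariate and 1 without the 5 libraries with that RNA (Ccl3, higher by 3.80). They gave 170 with the array spread as a covariate, 1 with the macrophage marker mean as a covariate (Gm6637, higher by 2.78) and 42 with sex as a covariate. Both single genes lie outside the 39 and were named after their values were seen. Fewer samples enter where libraries were left out; otherwise the cause was not tested.

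Same-numbered samples correlated from −0.036 to 0.53 in their deviations from the group means, with 3 of 6 pairs over 0.1. Such deviations also carry the spread within an array, which the first principal component tracked, and tumor 4 and mucosa 6 correlated at 0.47. The correlations therefore cannot tell whether the numbers mark animals. No label ties a number to an animal, so the numbers were not taken as pairs. Single genes follow numbers 2 and 3, though, and sex-linked RNA follows number 5. With the number as a replicate block 24 genes passed (16 of the 39), as a random replicate block 100 and in a replicate block without both number 6 samples 54 (23 of the 39). Among 6 tumor and 6 mucosa samples, 2 and 1 correlated best with their own number.

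The number of lists called was 18, against 4 with an estimated correlation, 11 with fry and 6 in an exact permutation of list means, and 15 to 19 when 1 sample was left out. It was 15 (9 of the 18) with the macrophage marker mean as a covariate, 14 (13 of the 18) with the array spread as a covariate and 24 (16 of the 18) without the 5 libraries with pancreatic enzyme RNA. Without the 5 libraries with pancreatic enzyme RNA the sign turned for Tgfbr2 (−0.041), Tff2 (−0.033), Rsad2 (−0.18), Skil (−0.027), the interferon response genes (−0.66) and the tissue dissociation stress genes (−0.41). With the macrophage marker mean as a covariate it turned for Adm (0.055), Utp20 (0.075), Mzb1 (−0.15), Col1a1 (−0.014) and Myh11 (−0.033). It also turned for the B and plasma cell markers (−0.095), the fibroblast markers (−0.19), the ribosome biogenesis genes (0.12) and the epithelial markers (0.24). Camera's direction, not the mean, turned for the absorptive colonocyte genes (mean −0.095) and the small intestine markers (−0.43). The cause was not tested. Dim genes near the floor of the arrays can hide differences.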

Other observations

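The tests in this part were chosen only after the values were seen.

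Many families of genes had mostly lower means in tumor epithelium, among them those for the mitochondrial respiratory chain and ribosomes, and no family passed camera with an estimated correlation. Grouped by the stem of their symbol, 41 of 43 Mrpl and 27 of 27 Mrps genes, which encode mitochondrial ribosomal proteins, had lower means (mean log2 differences −0.49 and −0.54). So did 21 of 22 Cox genes of cytochrome oxidase (−0.43), 13 of 13 Ndufa (−0.57) and 8 of 8 Ndufb genes (−0.65) of complex I. The thioredoxin-domain family Txndc (7 of 7 lower, −0.58), the aldo-keto reductases (Akr, 8 of 8 lower, −0.67) and the sulfotransferases (Sult, 5 of 5 lower, −1.02) showed the same sign. The lower means were not particular to mitochondria: the proteasome families Psmb and Psmd (10 of 10 and 14 of 14 lower), the nucleoporins (Nup, 15 of 15), the Lsm family (13 of 13), the RNA polymerase subunits (Polr, 24 of 25) and the cytosolic ribosomal proteins (Rpl, 34 of 39) went the same way. Of the families that went the other way, the annexins (Anxa, 6 of 9 higher) averaged 0.68 and the keratins (Krt, 22 of 32 higher) 0.27.

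Each of these families kept its sign with quantile normalization, with arrays centred on their median and with the array spread as a covariate. With that covariate the means of Mrpl (−0.30), Polr (−0.11), Psmd (−0.11), Nup (−0.12) and Lsm (−0.23) were smaller by over 1.5 times, from −0.49, −0.33, −0.37, −0.35 and −0.42. The families were stems of 8 to 100 genes, counted over members brighter than the median of all values. Of 265 with at least 5 such members, camera with the preset correlation called 58 (48 lower, 10 higher), and 0 passed with an estimated correlation (19 at an unadjusted p under 0.05). The share of lower means among all genes of that brightness is not given here, so the counts of lower members lack a base rate. The median log2 difference was −0.003 over all genes and −0.042 without the dimmest genes. Ints (15 of 15 lower), Cnot (9 of 9 lower) and Gbp (6 of 6 higher) were not called. A general lean of bright genes was not set apart from movement of single families. In limma none of the Mrps, Cox or Ndufb genes passed over all genes. The smallest adjusted p with an estimated correlation was 0.588, so the families' movement cannot be set apart from members that vary together between samples.

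Values of 2 genes followed the replicate number across the groups, in part. Gdpd3 stood at 4.65 in tumor 2 and 4.50 in mucosa 2 and between 7.39 and 9.33 in the other 10 libraries. H2-Q1, a class I MHC gene, stood at 6.61 in tumor 3, 6.68 in mucosa 3 and 5.95 in mucosa 6 and between 3.34 and 4.04 in the other 9. Gdpd3 sets both samples numbered 2 apart, and H2-Q1 both samples numbered 3 and also mucosa 6. Both genes were picked for their split, so they do not test whether the numbers mark animals.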
